A study of Homo sapiens with 16 samples.

How the data were processed

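RNA of T47D cells was measured in 16 libraries, 4 in each of 4 groups made by genotype (control guide or FAH knockout) and treatment (vehicle or 500 nM abemaciclib for 3 days). The titles in the labels gave each library its group and replicate number. Per the labels' protocols, RNA was extracted and sequenced by a commercial service, which made cDNA and tagged it by tagmentation, and cells grew in high-glucose medium with serum. Reads were aligned with STAR 2.7.11 and handled with SAMtools 1.22.1, genes were counted with featureCounts of Subread 2.1.1, quality was summarised with MultiQC 1.32, and the genome was GRCh38, per the submitters' processing notes. The annotation release, the strand setting, the treatment of reads with several matches and any use of molecular identifiers are not given in the sources used here, and neither are the guides or whether the knockout cells were a clone or a pool.

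The deposited values are counts per 1000000 assigned reads (CPM), in 1 table of 78986 genes or other features, and each library's column sums to 1000000. Of these, 36134 had no symbol and 2111 a repeated one, and gene IDs were then used. A spreadsheet had altered 51 symbols, and all 51 were restored by gene ID from a reference table, in which 61463 of the IDs were found. The 92 features of ERCC spike-in controls were left out of all tests. The smallest step between low values gave what 1 read is worth in each library, 0.0836 to 0.101 CPM, and so a depth of 9915776 to 11963094 assigned reads. With these steps 70.2 to 71.8% of the values above 0 were whole reads within 0.02 reads, and the rest were fractions, as when a read is shared between genes. Whole reads in all 16 libraries were recovered for 5270 of the 16218 tested genes (32.5%), too few for a test of counts, and none was run. A gene read as whole in 8 or fewer libraries was called uncertain. A fraction of 1 read is enough for a value not to be whole, so the mark does not give the size of the shared part. Without strand, reads of a gene and an overlapping antisense gene could not be told apart. At this depth 1 CPM stands for about 10 reads, so low genes carry a large counting error, and reads that are not counted by molecule are not independent of each other.

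CPM were taken as deposited to log2(CPM + 1). The 16218 genes with at least 1 CPM in at least 4 libraries were fitted with limma 3.58.1 in R 4.3.3, with all 16 libraries in a single fit of 4 group means, empirical Bayes with a trend, two-sided tests and Benjamini-Hochberg adjustment over all tested genes of a comparison. A gene was called at an adjusted p under 0.05. The 5 comparisons were knockout against control under each treatment, abemaciclib against vehicle in each genotype, and the interaction. FAH was also compared by an exact permutation test. The main design, the rule for naming genes, the 36 gene lists and most alternatives were set before the data were examined. The exceptions were voom on fractional reads, genes of whole reads alone and the tyrosine list without FAH, which were chosen after the data had been seen. The lists held genes of tyrosine breakdown, the cyclin D, CDK4/6 and RB axis, replication, mitosis, homologous recombination, p53 targets, estrogen response, luminal, basal, mesenchymal, leukocyte and HEK293-type markers, interferon response, antigen presentation, NF-kappaB targets, lysosome, cholesterol and fatty acid synthesis, fatty acid oxidation, glycolysis, the tricarboxylic acid cycle, the respiratory chain, mitochondrially encoded mRNAs, ribosomal proteins, histones, ribosome biogenesis, NRF2 and ATF4 targets, the unfolded protein response, heat shock, heme and iron, YAP targets, ERK output, growth factor receptors, apoptosis and metallothioneins. The 34 lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The estimate was 0.348 for ribosomal proteins and 0.388 for mitochondrially encoded mRNAs, so the preset value makes their p-values too small. Other lists also had larger p-values with the estimate. The interferon response list, estimated at 0.00746, went from camera adjusted p = 4.0e-37 to 4.3e-07 in knockout cells under vehicle. With a preset correlation camera draws its certainty from the number of genes and not of libraries. All such list p-values are therefore too small as a measure across libraries.

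Genes were named by rule. In each group comparison these were the 10 protein-coding genes with the largest increases and the 10 with the largest decreases among called genes of at least 5 mean CPM in the higher group whose groups did not overlap, and 5 and 5 for the interaction, without the overlap condition. To these came up to 4 called members of each called list in its direction and 2 against it, and in every comparison the tyrosine genes and a fixed set of cell cycle and hormone receptor genes. The text names some of them, taken by size, and some are not reported here. Restricting the rule to protein-coding genes was a reading of its exclusion of identifier-only names, made after the data had been seen. Genes named in the last part of the text outside this rule were chosen after their values were seen.

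Replicates were compared by the chi-square of their reads per gene over genes with at least 20 reads in a pair. It ranged from 1.30 to 4.68 over 24 pairs, so no pair of libraries was closer than sampling noise and all were kept. The fit was tested on simulated data for the knockout comparison under vehicle, with 16218 genes, a dispersion of 0.002 and 50 genes changed at each size. It recovered 60% of genes changed 1.25-fold, 88% at 1.5-fold, and 100% at 2-fold and 3-fold, and 11 of its 185 calls (5.95%) were unchanged genes. The simulated change of a list at 1.2-fold was called at a camera adjusted p = 2.8e-57, with 0 of 35 unchanged lists called. Simulated genes were drawn independently of each other with the same dispersion for all, and few of them were changed. These rates therefore show that the code works and do not give the false calls among the correlated genes and lists of the real data. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 CPM, median-of-ratios rescaling, quantile normalization, other empirical Bayes settings, library weights, fits of the compared groups alone, a replicate block, voom on fractional reads, genes of whole reads alone, the tyrosine list without FAH, and each library left out in turn. Chromosome positions came from GENCODE v29 on GRCh38 for 15138 of the 16218 tested genes (93.3%). Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.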

Results

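RNA was sequenced from T47D cells, an established human breast cancer line of luminal type that expresses the estrogen receptor. The cells carried either a control guide or a knockout of FAH, which encodes fumarylacetoacetate hydrolase, the enzyme of the last step of tyrosine breakdown. Each genotype was cultured for 3 days with vehicle or with 500 nM abemaciclib, an inhibitor of the cell cycle kinases CDK4 and CDK6, and the series concerns FAH in resistance to such inhibitors. Each of the 4 groups held 4 libraries, 16 in all, and the libraries held 9915776 to 11963094 reads assigned to genes. The first principal component of the tested genes carried 55.7% of the variance. It ran from vehicle libraries (-32.3 to -14.5) to abemaciclib libraries (17.2 to 29.9). Within each treatment it also set knockout above control libraries. They lay at -15.5 to -14.5 against -32.3 to -31.7 under vehicle, and at 29.2 to 29.9 against 17.2 to 18.1 under abemaciclib. The second component carried 18.1% and separated control (9.15 to 18.3) from knockout libraries (-18.3 to -8.50). Expression is given as counts per 1000000 assigned reads (CPM), mean ± SD of 4 libraries, and fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Those of gene lists at the preset correlation rest on the number of genes, and their small size is no measure of that spread.

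FAH, the targeted gene (ENSG00000103876, chromosome 15, 80152490 to 80186946 on the plus strand of GRCh38), was lower in all 8 knockout libraries than in any control library. Under vehicle the control libraries held 25.1, 27.5, 25.2 and 28.2 CPM of FAH and the knockout libraries 6.77, 6.53, 6.27 and 7.02. Under abemaciclib the control libraries held 23.4, 24.1, 25.8 and 22.6 CPM and the knockout libraries 5.03, 5.67, 6.79 and 5.54. The means were 6.65 ± 0.323 against 26.5 ± 1.57 CPM under vehicle (25.1% of control, log2 fold change -1.84, SE 0.0789, limma adjusted p = 4.5e-19). They were 5.76 ± 0.744 against 24.0 ± 1.35 CPM under abemaciclib (24.0%, -1.89, SE 0.0789, limma adjusted p = 3.4e-19). An exact two-sided permutation test gave p = 0.0286 within each treatment, the smallest that the 70 assignments of 4 against 4 libraries allow. The difference between abemaciclib and vehicle in FAH was -0.14 in control cells (limma adjusted p = 0.145) and -0.18 in knockout cells (limma adjusted p = 0.0639), neither of which passed the test. Without knockout abemaciclib replicate 3 the latter was -0.25 and passed (limma adjusted p = 0.0117), as it did with a pseudocount of 0.1 (limma adjusted p = 0.0481). The mRNA level says nothing of how much protein was left, since a guide can disrupt the reading frame of a transcript that is still counted.

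The list of phenylalanine and tyrosine breakdown held 8 tested genes beside FAH. GOT1, a cytosolic aspartate aminotransferase, fell by 0.23 log2 units in knockout cells under vehicle. ACAT1, which makes or splits acetoacetyl-CoA, fell by 0.19. GSTZ1, the enzyme just before FAH in the pathway, fell by 0.14. PCBD1 and GOT2 rose by 0.15 and 0.11. QDPR (-0.06), FAHD1 and FAHD2A (0.16, from partly shared reads) did not pass the test. FAHD1 and FAHD2A share a domain with FAH and are not enzymes of tyrosine breakdown. The counts below are therefore those of the list and not of the pathway alone. With FAH counted, 2 of 9 members rose and 4 fell, and 2 and 4 did when adjusted over the list alone. The list with FAH was called lower (camera adjusted p = 0.0275, and adjusted p = 0.0509 with an estimated correlation), a call that holds the knocked-out gene itself. Without FAH, a setting chosen after the data were seen, the other 8 were not called (2 higher and 3 lower, also when adjusted over the list alone, median -0.03, camera adjusted p = 0.253). The list held 14 genes, of which 5 were below the filter and not tested, so these results cover only a part of the pathway. Under abemaciclib the list with FAH was not called, with 2 of 9 members higher and 2 lower (2 and 3 adjusted over the list alone, median 0.02, camera adjusted p = 0.152). These counts were not stable. Among other settings, the call of FAHD2A as higher was lost after rescaling (limma adjusted p = 0.0820), quantile normalization (0.0706) and without control abemaciclib replicate 1 (0.149). GSTZ1 and QDPR passed as lower after rescaling (limma adjusted p = 0.0150 and 0.0351) and quantile normalization (0.0135 and 0.0430). Under vehicle PCBD1, GOT2 and GSTZ1 missed the threshold without the filter on low values, and PCBD1 and GOT2 also after rescaling or quantile normalization of the libraries and in limma without the trend. Each was lost without any 1 of 4 vehicle libraries. These were control replicate 3 or 4 or knockout replicate 2 or 3 for PCBD1 (limma adjusted p up to 0.0988). GOT2 was lost without replicate 2 or 3 of either genotype (0.177), and GSTZ1 without replicate 1 or 4 of either (0.0941).

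**Figure D1:**
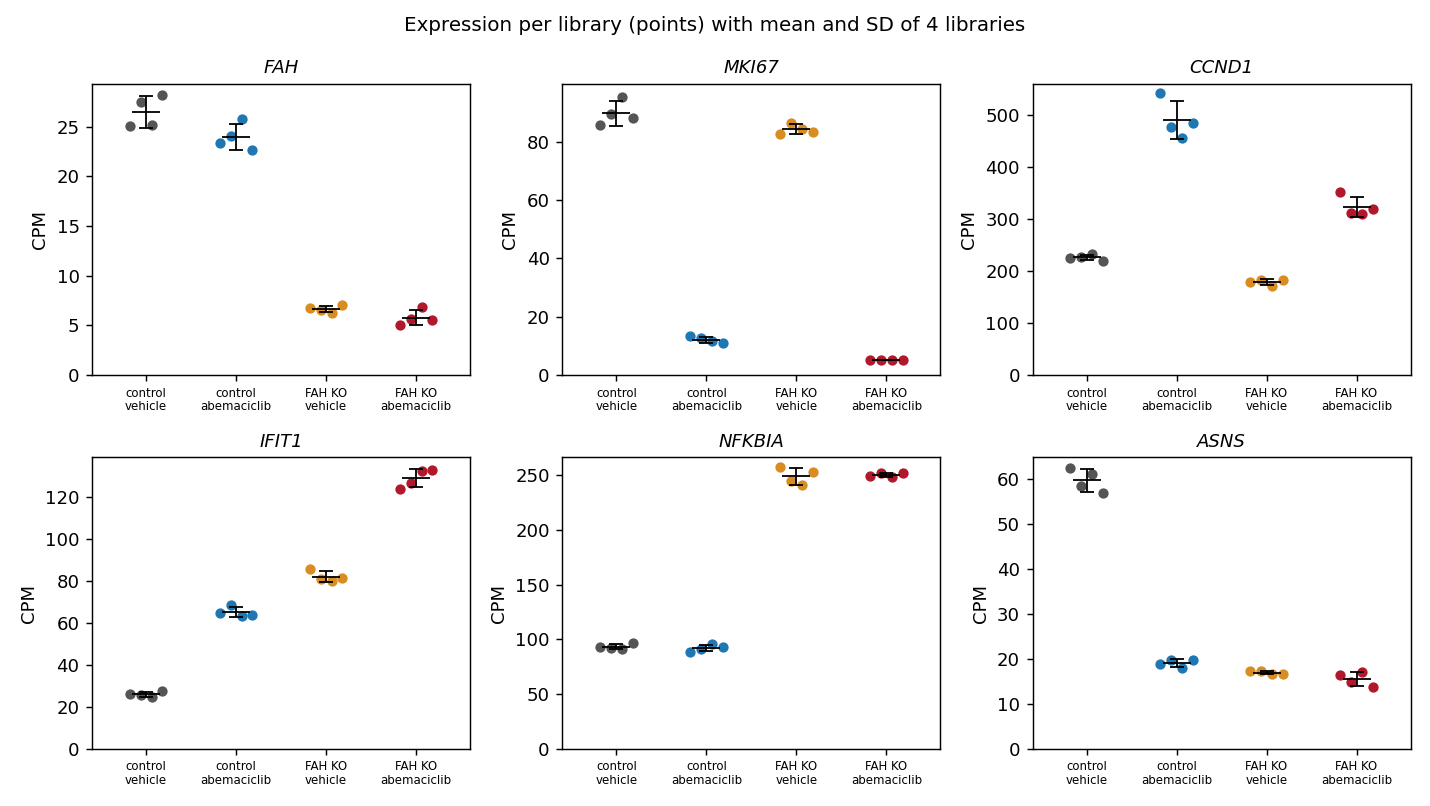
CPM of FAH, MKI67, CCND1, IFIT1, NFKBIA and ASNS in each of the 16 libraries (points) by group, with the mean and SD of 4 libraries (bars) and each gene on its own linear axis. FAH lies between 22.6 and 28.2 CPM in control libraries and between 5.03 and 7.02 CPM in knockout libraries.

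The knockout and control libraries under vehicle ask what accompanied the loss of FAH without the drug. Interferon-stimulated genes, which encode antiviral effectors and their regulators, were higher in knockout cells. Of 41 tested, 40 rose and 0 fell, and 40 and 0 did when adjusted over the list alone (median log2 fold change 0.98, camera adjusted p = 4.0e-37). OAS1, which senses double-stranded RNA, rose from 10.1 ± 0.667 to 39.6 ± 2.43 CPM (log2 fold change 1.87, SE 0.0627, limma adjusted p = 7.5e-22). ISG15, a ubiquitin-like modifier, rose from 52.9 ± 1.08 to 174 ± 5.22 CPM (1.70), and IFIT1, which binds foreign RNA, from 25.8 ± 1.23 to 81.9 ± 2.60 CPM (1.63). IFIT3 and XAF1 rose by 1.95 and 1.67. NF-kappaB targets and secreted factors rose in 16 of 21 tested genes and fell in 0, or 16 and 1 when adjusted over the list alone (median 0.62, camera adjusted p = 1.9e-09). RELB, a subunit of NF-kappaB itself, rose from 2.88 ± 0.522 to 15.1 ± 1.35 CPM (2.06). The inhibitor NFKBIA rose from 93.3 ± 2.1 to 249 ± 7.77 CPM (1.41), and the adhesion molecule ICAM1 from 2.77 ± 0.262 to 9.51 ± 0.703 CPM (1.48). Of 18 genes of MHC class I antigen presentation 15 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.54, camera adjusted p = 1.5e-09). The largest increases were those of the immunoproteasome subunit PSMB9 (0.98), the peptidase ERAP2 (0.88) and the peptide transporter TAP1 (0.67). The member that fell was the chaperone CALR (-0.09, from partly shared reads), whose value was 0.02 after quantile normalization and whose call was lost without control vehicle replicate 1 (limma adjusted p = 0.0503) and in limma without the trend (0.0940).

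ATF4 targets, which supply amino acids and their transporters under stress, were lower in knockout cells. Of 33 tested, 25 fell and 2 rose, and 25 and 3 did when adjusted over the list alone (median -0.53, camera adjusted p = 4.7e-27). Asparagine synthetase, ASNS, fell from 59.6 ± 2.49 to 16.9 ± 0.409 CPM (-1.76, SE 0.0630, limma adjusted p = 3.1e-21), and the cystine transporter SLC7A11 from 28.9 ± 0.783 to 8.94 ± 0.124 CPM (-1.59). The serine synthesis enzymes PHGDH (-1.47) and PSAT1 (-1.36) fell, as did PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate (-1.28). The members that rose were SLC38A2, an amino acid transporter, and the transcription factor ATF5 (0.25 and 0.21), the latter lost without control vehicle replicate 3 or knockout vehicle replicate 4 (limma adjusted p = 0.0902 and 0.0587). ATF5 was also lost after rescaling (0.15, limma adjusted p = 0.0908), after quantile normalization (0.109) and without the filter on low values (0.0712). Among other protein-coding genes of at least 5 CPM the largest decreases were those of S100A1 (-1.37), LIN28A (-1.31), TFF3 (-1.26) and MATN3 (-1.20). Those with the largest increases included PLEKHS1 (2.34), the transcription factor TFAP2B (1.70) and the metalloreductase-related STEAP1 (1.65). Cytosolic ribosomal protein mRNAs fell in 44 of 49 and rose in 0, or 46 and 0 when adjusted over the list alone, by small amounts (median -0.19, camera adjusted p = 5.1e-30, and adjusted p = 0.0145 with an estimated correlation). Protein-coding genes with numbered RPL or RPS symbols, a set not the same as the list, took 13.5 ± 0.132% of all reads in knockout libraries under vehicle. In control libraries under vehicle they took 15.8 ± 0.201%. Nuclear-encoded respiratory chain genes fell in 28 of 38 and rose in 1 (30 and 2 adjusted over the list alone, median -0.16, camera adjusted p = 3.0e-14, and adjusted p = 0.00438 with an estimated correlation), with COX8A, a subunit of complex IV, at -0.48.

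Mitotic and replication genes were moderately lower in knockout cells before any drug. Of 43 mitotic genes 29 fell and 0 rose (30 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 3.1e-15), among them the securin PTTG1 (-0.63) and the kinetochore gene NUF2 (-0.62). Of 42 replication genes 14 fell and 0 rose (14 and 0 adjusted over the list alone, median -0.10, camera adjusted p = 3.8e-06). The list of the cyclin D, CDK4/6 and RB axis was not called, with 4 of 24 members higher and 3 lower (4 and 3 adjusted over the list alone, median 0.04, camera adjusted p = 0.888), and its median was -0.02 after rescaling. Replication-dependent histones were not called either, with 4 of 18 higher and 4 lower (4 and 5 adjusted over the list alone, median 0.06, camera adjusted p = 0.782). In both of these lists the median was above 0 and the direction of camera lower. The proliferation marker MKI67 did not pass the test (-0.09), and passed after rescaling (-0.15, limma adjusted p = 0.0297). Cyclin D1, CCND1, which activates CDK4 and CDK6, fell from 226 ± 5.45 to 179 ± 5.28 CPM (-0.34), while CDK6 rose from 3.10 ± 0.385 to 5.67 ± 0.612 CPM (0.70). CDK4, RB1, E2F1, CCNE1, CCNE2 and CDK2 did not pass the test, with values between -0.11 and 0.21. The estrogen receptor gene ESR1 fell by 0.35, and its target list was lower, with 18 of 34 falling and 11 rising (19 and 12 adjusted over the list alone, median -0.14, camera adjusted p = 1.3e-04). The secreted proteins TFF1 (-0.69) and AGR2 (-0.80) fell, whereas IRS1, an adaptor of the insulin and IGF1 receptors, rose by 1.16. Luminal markers rose in 14 of 21 and fell in 5 (15 and 5 adjusted over the list alone, median 0.24, camera adjusted p = 1.2e-06). The keratins KRT8 (0.90) and KRT18 (0.85) were higher and the luminal transcription factor GATA3 lower (-0.31). Lysosome and autophagy genes rose in 26 of 44 and fell in 2 (28 and 3 adjusted over the list alone, median 0.22, camera adjusted p = 1.8e-06), with the autophagy receptor SQSTM1 at 0.60 and the transcription factor TFE3 at 0.57.

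Of 16218 tested genes, 3987 were higher and 2121 lower in knockout than in control libraries under vehicle (limma, adjusted over all genes), 85 and 32 of them by at least 2-fold. After median-of-ratios rescaling of the libraries 2832 were higher and 2975 lower. Of the 34 tested gene lists 22 were called, among them tyrosine breakdown through FAH, and 17 of the calls held with an estimated correlation. The other lists called higher were cholesterol synthesis (14 of 24 members higher and 3 lower, 16 and 3 adjusted over the list alone, camera adjusted p = 1.3e-04), YAP targets and heat shock proteins. YAP targets had 12 members higher and 0 lower of 17 (12 and 0 adjusted over the list alone, camera adjusted p = 1.4e-04), and heat shock proteins 12 and 1 of 18 (12 and 1 adjusted over the list alone, camera adjusted p = 1.3e-04). LSS and HMGCS1, enzymes of cholesterol synthesis, rose by 0.73 and 0.72, and the growth factor TGFB2 rose by 1.14. Lower lists were homologous recombination (11 of 22 members lower and 1 higher, 13 and 1 adjusted over the list alone, camera adjusted p = 3.3e-04), fatty acid oxidation and the tricarboxylic acid cycle. Fatty acid oxidation had 8 members lower and 0 higher of 22 (8 and 2 adjusted over the list alone, camera adjusted p = 7.4e-04), and the tricarboxylic acid cycle 11 and 6 of 24 (11 and 6 adjusted over the list alone, camera adjusted p = 0.00778). SUCLG2, a subunit of succinyl-CoA synthetase, fell by 0.42. Calls lost with an estimated correlation were those of growth factor receptors (higher, camera adjusted p = 0.0186, adjusted p = 0.262 with an estimated correlation) and fatty acid synthesis (higher, camera adjusted p = 0.0303, adjusted p = 0.130 with an estimated correlation). So were those of the unfolded protein response (lower, camera adjusted p = 0.0358, adjusted p = 0.146 with an estimated correlation) and glycolysis (lower, camera adjusted p = 0.0457, adjusted p = 0.0563 with an estimated correlation). Members rose and fell in 10 and 3 of 25, 9 and 3 of 21, 4 and 8 of 22, and 6 and 10 of 32 of these 4 lists. Adjusted over the list alone the counts were 12 and 3, 11 and 3, 4 and 9, and 7 and 10. Fatty acid synthesis also missed the threshold without control vehicle replicate 4 (camera adjusted p = 0.0591), the unfolded protein response without control vehicle replicate 2 or knockout vehicle replicate 3 (up to 0.0593). Glycolysis missed it without control vehicle replicate 1 or 4, control abemaciclib replicate 1 or knockout vehicle replicate 1 (up to 0.0849). With only genes of whole reads in all libraries, a setting chosen after the data were seen, calls were lost for estrogen receptor targets (camera adjusted p = 0.0559), lysosome genes (0.0663), respiratory chain genes (0.108), the tricarboxylic acid cycle (0.563) and cholesterol synthesis (0.722). Lost too were fatty acid synthesis (0.560), the unfolded protein response (0.252) and growth factor receptors (0.371), the last with its direction turned. Reads of IFIT3, KRT8, KRT18, HMGCS1, COX8A, SUCLG2, LIN28A, ATF5, CDK4 and ASNS were whole in 8 or fewer of 16 libraries, a sign that some reads were shared with overlapping or near-identical genes. Their values are uncertain by an amount that is not known, since the shared part may be small or large.

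The same genotypes under abemaciclib ask how knockout and control cells differ once CDK4 and CDK6 are inhibited. Proliferation genes were lower in knockout than in control cells under the drug. Of 43 mitotic genes 38 fell and 0 rose (39 and 0 adjusted over the list alone, median log2 fold change -0.60, camera adjusted p = 8.5e-40). Of 42 replication genes 39 fell and 0 rose (40 and 0 adjusted over the list alone, median -0.47, camera adjusted p = 3.9e-36). MKI67 was at 5.13 ± 0.0876 CPM in knockout and 12.1 ± 0.991 CPM in control libraries (-1.09, SE 0.0573, limma adjusted p = 1.2e-16). The ribonucleotide reductase subunit RRM2 (-1.47), the transcription factor MYBL2 (-1.3), thymidine kinase TK1 (-1.30) and the mitotic kinase CDK1 (-1.11) were lower as well. In the list of the cyclin D, CDK4/6 and RB axis 11 of 24 members were lower and 4 higher (11 and 4 adjusted over the list alone, median -0.16, camera adjusted p = 0.00174). Cyclin E2, CCNE2, (-1.18) and E2F1, a transcription factor of S phase entry (-0.84), were lower, and CCND1 was at 323 ± 19.4 against 490 ± 36.8 CPM (-0.60). CDK6 (0.53) and the CDK inhibitor CDKN2B (1.17) were higher, as was MYC (0.36). CDK4, CDK2, RB1, CCNE1, CDKN1A and CDKN1B did not pass the test, with values between -0.18 and 0.02. Homologous recombination and Fanconi repair genes were lower in 17 of 22 and higher in 0 (18 and 0 adjusted over the list alone, median -0.47, camera adjusted p = 1.3e-12). The nuclease EXO1 was at -1.07.

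Interferon-stimulated genes and NF-kappaB targets were again higher in knockout cells. The interferon list had 34 of 41 members higher and 1 lower (35 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 3.8e-20). OAS1 was at 1.29, IFIT3 at 1.36, and IFI27, the member that was lower, at -0.33. The NF-kappaB list had 14 of 21 higher and 0 lower (14 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 3.9e-11), with RELB at 1.77, NFKBIA at 1.43, ICAM1 at 1.30 and the chemokine CCL2 at 1.02. Antigen presentation genes were higher in 15 of 18 and lower in 2 (15 and 2 adjusted over the list alone, median 0.37, camera adjusted p = 1.4e-08), with PSMB9 at 1.28. Among protein-coding genes of at least 5 CPM the largest increases also held PLEKHS1 (1.73), STEAP1 (1.57), TFAP2B (1.53), the transcriptional cofactor LMO4 (1.42) and the collagen COL16A1 (1.29). The largest decreases after FAH were SERPINI1 (-1.59), the transporter ABCC12 (-1.55), the folate receptor FOLR1 (-1.52), SIPA1 (-1.51) and LIN28A (-1.50). Estrogen receptor targets were lower in 20 of 34 and higher in 6 (20 and 7 adjusted over the list alone, median -0.27, camera adjusted p = 1.6e-10), with TFF3 at -1.47 and the transcription factor MYB at -0.99. ESR1 (-0.34) and the progesterone receptor PGR (-0.29) were lower. ATF4 targets were lower in 19 of 33 and higher in 3 (20 and 3 adjusted over the list alone, median -0.16, camera adjusted p = 8.8e-08), with PHGDH at -0.97 and the mitochondrial folate enzyme ALDH1L2 at -0.79. GDF15, a secreted stress factor, was higher (0.51). Mitochondrially encoded mRNAs were lower in 8 of 13 and higher in 1 (8 and 1 adjusted over the list alone, median -0.16, camera adjusted p = 7.9e-09, and adjusted p = 0.0375 with an estimated correlation). Reads of mitochondrial genes, a sign of RNA quality, took 13.4 ± 0.274% of knockout and 14.9 ± 0.304% of control libraries under abemaciclib.

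Across all tested genes, 3020 were higher and 1837 lower in knockout cells under abemaciclib (limma), 46 and 56 of them by at least 2-fold, and after rescaling 2126 were higher and 2407 lower. Of the 34 lists 25 were called and 19 calls held with an estimated correlation. The other higher calls that held included YAP targets (10 higher and 0 lower of 17, 12 and 1 adjusted over the list alone, camera adjusted p = 1.6e-06) and cholesterol synthesis (15 and 0 of 24, 16 and 0 adjusted over the list alone, camera adjusted p = 2.2e-08). Heat shock proteins (12 higher and 0 lower of 18, 13 and 0 adjusted over the list alone, camera adjusted p = 2.8e-05) and ribosome biogenesis (14 and 0 of 34, 16 and 1 adjusted over the list alone, camera adjusted p = 7.0e-04) were higher too. The rest were p53 targets (11 higher and 3 lower of 25, 11 and 3 adjusted over the list alone, camera adjusted p = 0.00261), NRF2 targets (9 and 1 of 22, 10 and 1 adjusted over the list alone, camera adjusted p = 0.00825) and luminal markers (12 and 6 of 21, 13 and 6 adjusted over the list alone, camera adjusted p = 0.0112). The oxidoreductase TP53I3 and the apoptosis effector BAX, both p53 targets, were higher by 1.02 and 0.55, and PIR, an NRF2 target, was higher by 0.83. Fatty acid oxidation (9 lower and 0 higher of 22, 9 and 1 adjusted over the list alone, camera adjusted p = 2.0e-04) was lower. So was glycolysis (15 and 4 of 32, 16 and 4 adjusted over the list alone, camera adjusted p = 2.0e-04). The lactate exporter SLC16A3 was lower (-1.13). Lost with an estimated correlation were the calls of ribosomal proteins (lower), fatty acid synthesis, replication-dependent histones and lysosome genes (higher), and the unfolded protein response and the respiratory chain (lower). They were called at camera adjusted p = 1.6e-04, 0.00935, 0.0138, 0.0183, 0.0275 and 0.0308, and had adjusted p = 0.304, 0.0689, 0.0554, 0.127, 0.127 and 0.286 with an estimated correlation. Members of these lists were higher and lower in 3 and 18 of 49, 8 and 0 of 21, 10 and 1 of 18, 14 and 4 of 44, 1 and 7 of 22, and 4 and 11 of 38. Adjusted over the list alone they were 3 and 20, 9 and 0, 10 and 2, 14 and 4, 1 and 7, and 4 and 11. The lysosome call also missed the threshold without control abemaciclib replicate 1 (adjusted p = 0.0648), that of the unfolded protein response without control abemaciclib replicate 2 (0.0519). That of the respiratory chain missed it without control abemaciclib replicate 3 or 4 or knockout abemaciclib replicate 4 (up to 0.131). With only genes of whole reads, the calls of p53 targets (camera adjusted p = 0.119) and NRF2 targets (0.282) were lost, and so were those of the unfolded protein response (0.160), fatty acid synthesis (0.241), histones (0.415), lysosome genes (0.576) and the respiratory chain (0.583). Control abemaciclib replicate 1 differed more from its group than any other library (chi-square per gene 2.85 to 4.68 against the other 3, and 1.30 to 2.49 in the other 21 pairs of replicates). Without it 3068 genes were higher and 1627 lower (limma). The values of RRM2, PGR, CDK4, IFIT3, LIN28A and TP53I3 are uncertain because of shared reads.

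**Figure D2:**
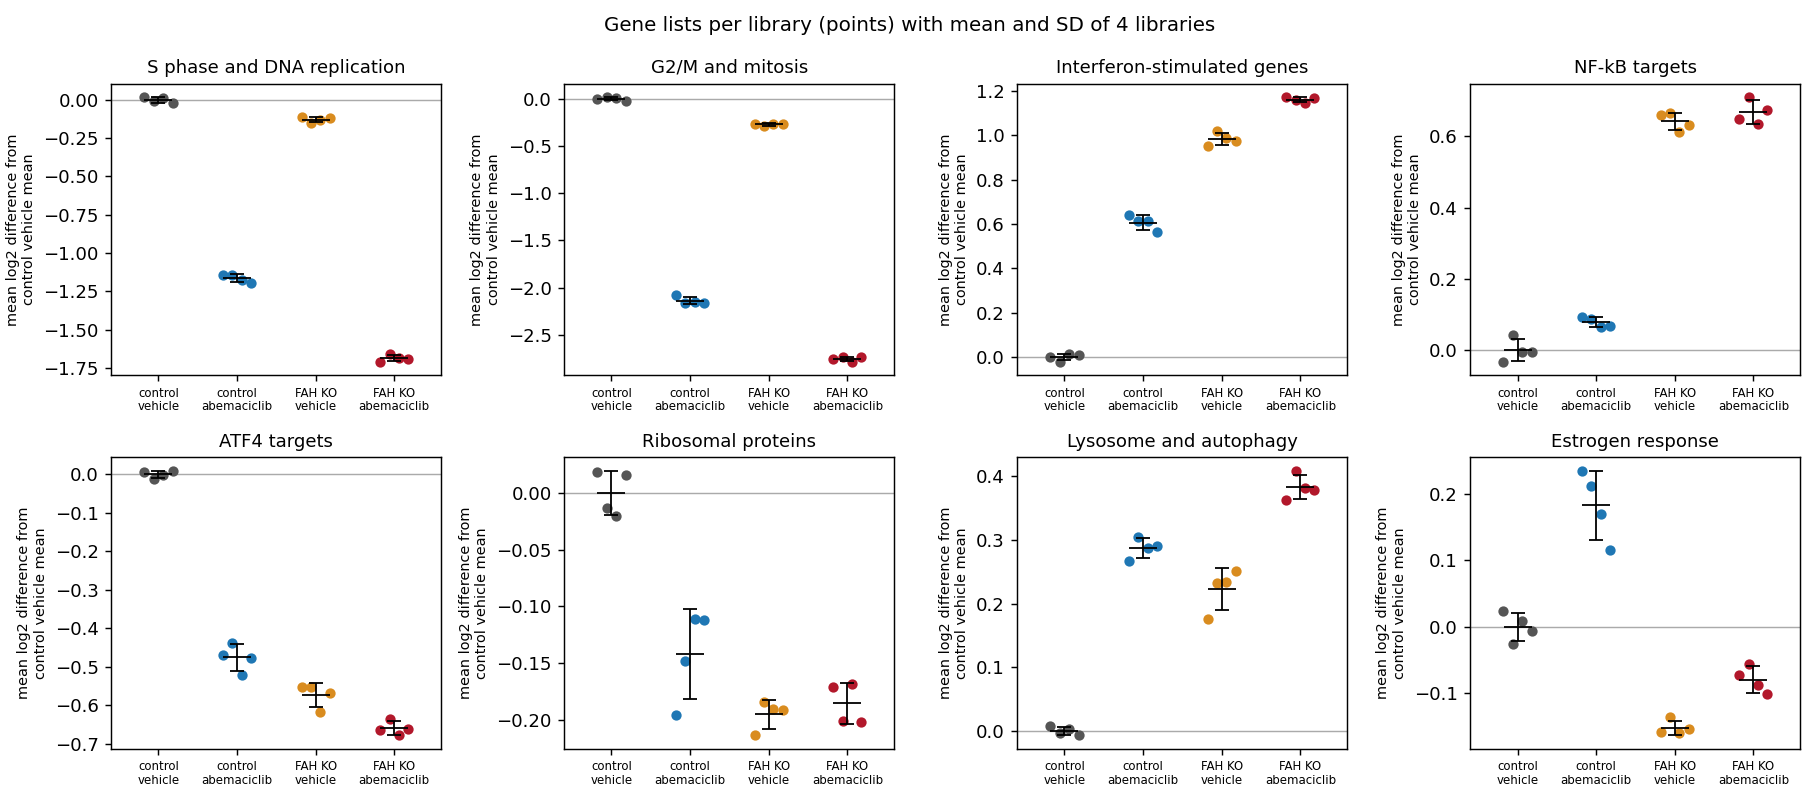
Mean log2 difference from the control vehicle mean over the tested members of 8 gene lists, for each of the 16 libraries (points) with the mean and SD of 4 libraries (bars). Mitotic genes sit at -2.14 ± 0.0408 in control and -2.75 ± 0.0223 in knockout libraries under abemaciclib, and interferon-stimulated genes at 0.61 ± 0.0325 and 1.16 ± 0.0124.

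In control cells, abemaciclib against vehicle asks what the drug itself did, and the largest changes were decreases of genes of the dividing cell. Every tested mitotic gene fell (43 of 43, 43 adjusted over the list alone, median -2.14, camera adjusted p = 2.6e-48). So did every tested replication gene (42 of 42, 42 adjusted over the list alone, median -0.97, camera adjusted p = 2.1e-30). MKI67 fell from 89.6 ± 4.16 to 12.1 ± 0.991 CPM (-2.80, SE 0.0573, limma adjusted p = 6.8e-29). The mitotic kinases AURKB (-3.53) and PLK1 (-2.85), cyclin A2, CCNA2 (-3.12), the kinesin KIF20A (-3.16) and RRM2 (-3.00) were among the largest decreases, with NEURL1B (-3.01) and the neuropeptide NMU (-3.01). Replication-dependent histones fell in 13 of 18 and rose in 0 (13 and 0 adjusted over the list alone, median -0.57, camera adjusted p = 6.8e-05). Homologous recombination genes fell in 20 of 22 and rose in 1 (20 and 1 adjusted over the list alone, median -0.88, camera adjusted p = 6.0e-08). In the cyclin D, CDK4/6 and RB axis 17 of 24 members fell and 4 rose (17 and 5 adjusted over the list alone, median -0.46, camera adjusted p = 4.6e-04). CCND1 rose from 226 ± 5.45 to 490 ± 36.8 CPM (1.11) and CDK6 rose by 0.87, whereas CCNE2 (-1.96), E2F1 (-1.07), CDK2 (-0.82), CDK4 (-0.32) and RB1 (-0.28) fell. The CDK inhibitor CDKN1A, itself a p53 target, fell by 1.08, and p53 targets fell in 18 of 25 and rose in 3 (18 and 3 adjusted over the list alone, median -0.45, camera adjusted p = 7.7e-04).

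Interferon-stimulated genes rose with the drug in control cells as well, 36 of 41 with 1 falling (36 and 1 adjusted over the list alone, median 0.65, camera adjusted p = 9.8e-19), led by IFI27 (1.71), IFIT1 (1.30) and OAS2 (1.2). Luminal markers rose in 17 of 21 and fell in 1 (18 and 1 adjusted over the list alone, median 0.32, camera adjusted p = 9.6e-12), with the secreted protein PIP rising from 569 ± 7.84 to 2040 ± 78.3 CPM (1.84). The member that fell was EPCAM (-0.10), which missed the threshold after rescaling (-0.03, limma adjusted p = 0.488) and was 0.03 after quantile normalization. The keratin KRT15 (1.77), the kinase SGK1 (1.61) and BCAS1 (1.57) were among the largest increases. Lysosome and autophagy genes rose in 31 of 44 and fell in 3 (33 and 3 adjusted over the list alone, median 0.30, camera adjusted p = 9.6e-12). The membrane glycoprotein GPNMB was at 1.2 and the protease cathepsin D, CTSD, at 0.68. Estrogen receptor targets rose in 17 of 34 and fell in 6 (17 and 6 adjusted over the list alone, median 0.13, camera adjusted p = 1.6e-04), with IRS1 at 1.09 and TFF3 at 0.66. ESR1 itself did not pass the test (0.03), and passed after rescaling (0.10, limma adjusted p = 0.0384) and after quantile normalization (0.14, limma adjusted p = 0.00314). YAP targets rose in 9 of 17 and fell in 0 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00126). ATF4 targets fell in 22 of 33 and rose in 5 (23 and 5 adjusted over the list alone, median -0.34, camera adjusted p = 5.8e-06). SLC7A11 went from 28.9 ± 0.783 to 7.51 ± 0.775 CPM (-1.82), ASNS from 59.6 ± 2.49 to 19.1 ± 0.873 CPM (-1.59), and PHGDH and PSAT1 fell too (-1.62 and -1.43). Ribosome biogenesis genes fell in 27 of 34 and rose in 0 (27 and 0 adjusted over the list alone, median -0.27, camera adjusted p = 1.1e-05). Respiratory chain genes fell in 29 of 38 and rose in 0 (29 and 2 adjusted over the list alone, median -0.21, camera adjusted p = 1.1e-06, and adjusted p = 0.0371 with an estimated correlation). MYC fell by 0.22.

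Mitochondrially encoded mRNAs rose in 12 of 13 and fell in 1 (12 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 1.4e-11, and adjusted p = 0.0270 with an estimated correlation). The share of reads on mitochondrial genes was 14.9 ± 0.304% with the drug and 10.9 ± 0.330% with vehicle in control cells. Ribosomal protein genes fell in 33 of 49 and rose in 2 (34 and 2 adjusted over the list alone, median -0.14, camera adjusted p = 1.1e-05), a call lost at adjusted p = 0.302 with an estimated correlation. The share of reads on all numbered RPL and RPS genes, a set not the same as the list, was 14.2 ± 0.402% against 15.8 ± 0.201%. Calls of growth factor receptors and PI3K signalling (higher, 12 higher and 4 lower of 25), cholesterol synthesis (lower, 5 and 15 of 24), the unfolded protein response (higher, 9 and 4 of 22) and antigen presentation (higher, 9 and 4 of 18) were also lost. They were called at camera adjusted p = 0.00143, 0.0109, 0.0229 and 0.0481, and had adjusted p = 0.159, 0.0818, 0.129 and 0.159 with an estimated correlation. Adjusted over the list alone these counts were 12 and 4, 5 and 15, 9 and 4, and 9 and 4. Across all genes 3181 were higher and 5039 lower (limma), 93 and 339 of them by at least 2-fold, and after rescaling 4159 were higher and 4024 lower. Without control abemaciclib replicate 1 they were 2892 and 5190. Of the 34 lists 20 were called and 15 held with an estimated correlation. The antigen presentation call missed the threshold without control vehicle replicate 2 or 3, control abemaciclib replicate 2 or 4 or knockout abemaciclib replicate 2 (camera adjusted p up to 0.0843). Calls lost with only genes of whole reads were those of p53 targets (camera adjusted p = 0.0901), ribosome biogenesis (0.120), the respiratory chain (0.158), estrogen receptor targets (0.229), growth factor receptors (0.154) and the unfolded protein response (0.398). The values of RRM2, CDK4, GPNMB, CTSD and ASNS are uncertain because of shared reads.

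In knockout cells, abemaciclib against vehicle gave the same direction for the cell cycle lists. Every tested mitotic gene fell (43 of 43, 43 adjusted over the list alone, median -2.57, camera adjusted p = 1.0e-74), as did every replication gene (42 of 42, 42 adjusted over the list alone, median -1.34, camera adjusted p = 3.6e-55). MKI67 fell from 84.2 ± 1.67 to 5.13 ± 0.0876 CPM (-3.80, SE 0.0573, limma adjusted p = 5.5e-33), RRM2 fell by more than any other gene named here (-4.19), and AURKB (-4.14), MYBL2 (-3.96) and KIF20A (-3.95) fell next to it. Homologous recombination genes fell in 20 of 22 and rose in 1 (20 and 1 adjusted over the list alone, median -1.2, camera adjusted p = 7.4e-15). Replication-dependent histones fell in 11 of 18, with 0 rising (11 and 1 adjusted over the list alone, camera adjusted p = 0.00419). In the cyclin D, CDK4/6 and RB axis 16 of 24 members fell and 3 rose (17 and 3 adjusted over the list alone, median -0.56, camera adjusted p = 9.5e-07). CCNE2 (-3.03) and E2F1 (-1.97) fell, and CCND1 (0.85), CDK6 (0.70) and CDKN2B (0.84) rose. Luminal markers rose in 16 of 21 and fell in 1 (16 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 4.1e-14). Lysosome genes rose in 25 of 44 with 2 falling (25 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 1.3e-10), as did interferon-stimulated genes in 20 of 41 with 3 falling (21 and 4 adjusted over the list alone, median 0.19, camera adjusted p = 6.0e-08). YAP targets rose in 10 of 17 and fell in 1 (12 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 8.6e-07). The matricellular proteins CCN1 (1.3) and CCN2 (1.06) were among the largest increases beside KRT15 (1.35), NABP1 (1.24) and SGK1 (1.14). The ATF4 list was not called: 12 of 33 members fell and 7 rose (12 and 7 adjusted over the list alone, median -0.10, camera adjusted p = 0.820).

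Across all genes 1780 were higher and 4444 lower with abemaciclib in knockout cells (limma), 9 and 316 of them by at least 2-fold. After rescaling 3144 were higher and 2905 lower. Of the 34 lists 17 were called, and 9 held with an estimated correlation. Lost with it were the calls, all higher except where said, of mitochondrially encoded mRNAs (9 higher and 1 lower of 13), estrogen receptor targets (13 and 8 of 34), p53 targets (lower, 4 and 16 of 25) and the unfolded protein response (9 and 1 of 22). Lost as well were those of ribosome biogenesis (lower, 0 and 18 of 34), cholesterol synthesis (lower, 4 and 14 of 24), ERK pathway output (8 and 6 of 20) and ribosomal proteins (8 and 6 of 49). They were called at camera adjusted p = 9.5e-07, 0.00158, 0.00274, 0.00308, 0.00460, 0.00770, 0.0307 and 0.0316, and had adjusted p = 0.0908, 0.0826, 0.050, 0.0622, 0.0977, 0.0776, 0.0622 and 0.627 with an estimated correlation. Adjusted over the list alone their counts were 9 and 1, 13 and 8, 4 and 17, 9 and 2, 0 and 20, 4 and 15, 8 and 6, and 7 and 6. The ERK output call was lost after rescaling (camera adjusted p = 0.0571) and the ribosomal protein call without knockout vehicle replicate 1 or knockout abemaciclib replicate 1 or 3 (up to 0.0938). With only genes of whole reads the lysosome call was lost (camera adjusted p = 0.238), as were those of p53 targets (0.397), estrogen receptor targets (0.397), the unfolded protein response (0.397), ERK output (0.397) and ribosome biogenesis (0.779). Mitochondrial reads took 13.4 ± 0.274% with the drug and 11.7 ± 0.196% with vehicle in knockout cells. The values of RRM2, NABP1 and ribosomal protein genes are uncertain because of shared reads.

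The interaction, the abemaciclib effect in knockout cells minus that in control cells, asks whether the drug response depended on genotype. Replication and mitotic genes fell further in knockout cells. The interaction was negative and called in 25 of 42 replication genes and positive in 0 (30 and 0 adjusted over the list alone, median -0.33, camera adjusted p = 4.2e-23). It was negative in 21 and positive in 1 of 43 mitotic genes (26 and 2 adjusted over the list alone, median -0.34, camera adjusted p = 2.7e-14). RRM2 (-1.20), MYBL2 (-1.12), the checkpoint mediator CLSPN (-1.11), CCNE2 (-1.07) and MKI67 (-1.0, SE 0.0811, limma adjusted p = 1.0e-10) led this group. Over the 85 genes of both lists the median abemaciclib effect was -1.60 in control and -1.86 in knockout cells, and 76 of the 85 went further down in knockout cells. The cyclin D, CDK4/6 and RB axis had 6 of 24 members lower and 2 higher (10 and 2 adjusted over the list alone, median -0.22, camera adjusted p = 0.00158). E2F1 was at -0.90, CCND1 at -0.26 (missing the threshold in limma without the trend, adjusted p = 0.0558) and MYC at 0.28. Homologous recombination genes were lower in 5 of 22 and higher in 0 (10 and 0 adjusted over the list alone, camera adjusted p = 7.9e-05). FAH itself (-0.05), CDK6 (-0.17), CDK4 (0.05) and ESR1 (0.01) did not pass the test of the interaction.

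ATF4 targets went the other way: the interaction was positive and called in 22 of 33 and negative in 0 (24 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 7.6e-28). ASNS held 59.6 and 19.1 CPM in control cells and 16.9 and 15.5 CPM in knockout cells with vehicle and abemaciclib (interaction 1.47, SE 0.0890, limma adjusted p = 6.5e-14). SLC7A11 (1.44), GDF15 (1.04) and PSAT1 (0.98) followed, and XAGE2 (0.95) completed the 5 named genes with the largest positive interactions. Ribosomal proteins were positive in 29 of 49 and negative in 0 (38 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 1.5e-27), and respiratory chain genes in 18 and 0 of 38 (21 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 6.6e-13). With an estimated correlation these 2 lists had camera adjusted p = 0.0224 and 0.0108, much nearer the threshold. Ribosome biogenesis genes were positive in 5 and negative in 0 of 34 (7 and 0 adjusted over the list alone, camera adjusted p = 4.5e-05). Histones were positive in 3 and negative in 0 of 18 (3 and 0 adjusted over the list alone, camera adjusted p = 3.3e-04). Some of these histone calls were lost with a pseudocount of 5 (limma adjusted p = 0.0551 and 0.0926), without the filter (0.174 and 0.176) and without the trend (0.0866 and 0.0835). They were also lost without knockout abemaciclib replicate 3 (0.0858 and 0.124), among other single libraries. The rise of interferon-stimulated genes with the drug was smaller in knockout cells, with a negative interaction in 25 of 41 and a positive one in 0 (29 and 0 adjusted over the list alone, median -0.41, camera adjusted p = 2.0e-25), and IFI27 at -1.10. Mitochondrially encoded mRNAs were negative in 9 of 13 and positive in 0 (11 and 0 adjusted over the list alone, median -0.28, camera adjusted p = 4.1e-16, and adjusted p = 0.0123 with an estimated correlation). The share of mitochondrial reads went from 10.9 to 14.9% with the drug in control and from 11.7 to 13.4% in knockout cells. Lysosome genes (12 lower and 1 higher of 44, 15 and 1 adjusted over the list alone, camera adjusted p = 5.4e-05) and luminal markers (7 and 0 of 21, 9 and 2 adjusted over the list alone, camera adjusted p = 5.1e-04) were negative, with PIP at -1.10. The calls of growth factor receptors (6 lower and 0 higher of 25, 7 and 0 adjusted over the list alone) and estrogen receptor targets (10 and 5 of 34, 15 and 6 adjusted over the list alone) were negative at camera adjusted p = 2.8e-04 and 0.0309. They were lost at adjusted p = 0.133 and 0.227 with an estimated correlation. In all, 759 genes had a positive and 999 a negative interaction (limma), 7 and 17 of them of at least 2-fold, or 878 and 897 after rescaling and 761 and 899 without control abemaciclib replicate 1. Of the 34 lists 15 were called, and 13 of the 15 list calls held with an estimated correlation. With only genes of whole reads the calls of lysosome genes (camera adjusted p = 0.117), respiratory chain genes (0.190), growth factor receptors (0.190) and estrogen receptor targets (0.441) were lost. The values of RRM2, CDK4 and ASNS are uncertain because of shared reads, and so are those of mitochondrial and ribosomal protein genes, most of whose values were not whole reads.

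**Figure D3:**
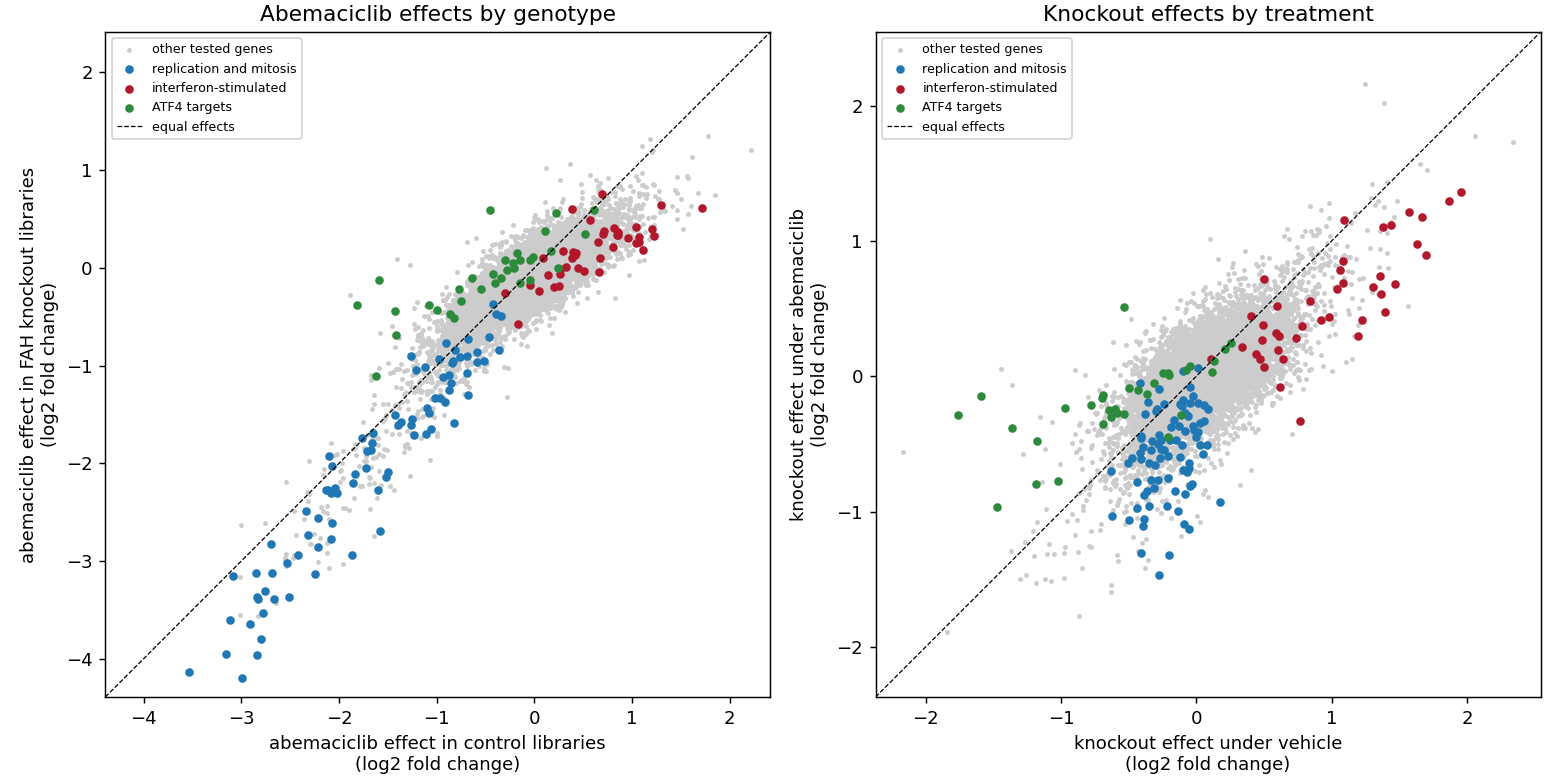
Log2 fold changes of the 16218 tested genes (points), with abemaciclib effects in knockout against control libraries on the left and knockout effects under abemaciclib against vehicle on the right; the dashed line marks equal effects. Replication and mitotic genes (blue) lie below the line of equal abemaciclib effects in 76 of 85 cases.

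The effects of abemaciclib in the 2 genotypes were correlated across genes (Pearson r = 0.851, Spearman rho = 0.773, slope 0.762 of knockout on control), and genes are not independent replicates. Of the genes called higher with the drug, 1496 were shared by both genotypes, against 349 for independent lists of these sizes, and of those called lower 3485 were shared, against 1381. Another 28 genes rose in control and fell in knockout cells, and 19 did the opposite. The knockout effects under vehicle and abemaciclib were also correlated across genes (r = 0.666, rho = 0.587, slope 0.623). Of the genes called higher in knockout cells 1962 were shared by both treatments, against 742 for independent lists, and of those called lower 1007 against 240, while 55 rose under vehicle and fell under abemaciclib and 68 did the opposite. Neither pair of comparisons shares a library. Among the calls of named genes in the 4 group comparisons, the libraries of the groups compared overlapped for GOT2 and GSTZ1 in knockout cells under vehicle and for FOS and JUNB with abemaciclib in knockout cells. The test and the naming rule both favour genes whose groups do not overlap.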

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

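The test on leukocyte markers was chosen only after the result it bears on was seen. Interferon-stimulated genes and NF-kappaB targets were higher in knockout cells, with list medians of 0.98 and 0.62 under vehicle and 0.47 and 0.43 under abemaciclib. Library scaling as the whole cause is argued against by the smallest of these 4 medians after median-of-ratios rescaling, 0.384. Copy number of their chromosome regions would move the neighbours too, but the 20 nearest tested genes of the 56 higher members had a median knockout effect, averaged over both treatments, of 0.0822 (bootstrap interval 0.0565 to 0.0950 in 2000 resamples), against 0.785 for the members. Leukocytes in the knockout libraries would raise leukocyte markers, of which 8 of 21 were tested, but the higher of their 2 medians was -0.0311, and LCP1 and SRGN, the most abundant, held 4.96 and 2.69 CPM in knockout and 5.53 and 5.17 CPM in control libraries under vehicle. A response to the loss of FAH stays open as a hypothesis, and so does any other difference between the knockout and control cultures, which these groups do not separate.

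Replication and mitotic genes fell further with abemaciclib in knockout than in control cells, with a median interaction of -0.33 over 85 genes. The median was -0.38 with a pseudocount of 0.1, which decides nothing about low values, since a pseudocount compresses falls most where values are lowest, here in knockout cells under the drug. No single library made the difference, since the highest of the 16 medians without 1 library was -0.296, and it was -0.32 after rescaling of the libraries. A candidate explanation, as a hypothesis, is that the loss of FAH deepened the response to the drug. Whether other differences between the cultures did so was not tested.

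ATF4 targets fell with abemaciclib in control cells and were not called in knockout cells, where they were already lower under vehicle (median -0.53), and the interaction was positive for them and for ribosomal protein genes. Against shared reads as the cause, the 10 ATF4 members with whole reads in all 16 libraries had a median interaction of 0.36. Against library scaling and a single library, the ATF4 median was 0.34 after rescaling and 0.31 at the lowest without 1 library, and that of ribosomal protein genes 0.17 and 0.13. For ribosomal protein genes, shared reads cannot be told apart from a change of the genes, because 0 members had whole reads in all 16 libraries. That the loss of FAH itself lowers ATF4 targets and so leaves less for the drug to lower stays open, as a hypothesis that was not tested.

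Chance assignment of these 16 libraries to the groups is argued against, and not excluded, for the number of genes called in each comparison. Splits of the libraries say nothing of chance differences between cultures. In each of the 4 group comparisons 1 of the 35 splits of the 8 libraries, the real one, gave as many calls, the smallest share that 35 splits allow. The other splits hold the group difference within their spread, so few calls were to be had from them. The gap in calls therefore adds nothing to the rank of the real split. The real and the highest other split called 6108 and 0 genes for the knockout under vehicle and 4857 and 1 under abemaciclib. For abemaciclib they called 8220 and 0 genes in control and 6224 and 0 in knockout cells. For the interaction, after removal of the additive effects, 1 of 100 splits of the 16 libraries, the real one, gave as many, 1758 genes against 451 in the highest other.

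The abemaciclib effect differed between genotypes by the interaction test, with 759 genes positive and 999 negative. Positive medians were 0.33 for ATF4 targets, 0.26 for histones, 0.16 for ribosomal proteins, 0.12 for the respiratory chain and 0.0907 for ribosome biogenesis. Negative ones were -0.41 for interferon-stimulated genes, -0.34 for mitosis, -0.33 for replication, -0.28 for mitochondrially encoded mRNAs and -0.22 for the cyclin D, CDK4/6 and RB axis. Others were -0.19 for homologous recombination, -0.16 for growth factor receptors, -0.13 for luminal markers, and -0.11 and -0.11 for lysosome genes and estrogen receptor targets. The calls of growth factor receptors and estrogen receptor targets were lost at adjusted p = 0.133 and 0.227 with an estimated correlation (camera). Among named genes the interaction was 1.47 for ASNS, 1.44 for SLC7A11, 1.04 for GDF15, 0.98 for PSAT1, 0.95 for XAGE2 and 0.28 for MYC. It was -1.20 for RRM2, -1.12 for MYBL2, -1.11 for CLSPN, -1.10 for IFI27, -1.10 for PIP, -1.07 for CCNE2, -1.0 for MKI67, -0.90 for E2F1 and -0.26 for CCND1.

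Some libraries lay far from the other 3 of their group by Dixon's ratio, in 1 of 36 groups of library measures, 3 of 136 of gene lists and 20 of 456 of named genes. Chance alone gives about 1 in 20 groups. Control abemaciclib replicate 1 had 87.1% of its reads on protein-coding genes (nearest other 87.8%). It had the highest mitotic list level of its group (-2.08, nearest other -2.15) and the highest heme and iron list level (0.0210, nearest other -0.0368). It also had the highest CPM of its group for ABCC12 (15.1), KRT15 (72.6) and TFAP2B (2.52) and the lowest for FAHD1 (56.5) and SIPA1 (10.5). Control abemaciclib replicate 3 had the lowest CPM of CALR (692), CCNE2 (4.84) and IFIT3 (14.8). Among control vehicle libraries replicate 1 was highest for PSMB9 (14.9 CPM), TFAP2B (1.21) and XAF1 (1.82), replicate 2 was highest for RB1 (37.7), and replicates 3 and 4 were lowest for SLC30A1 (17.3) and FOS (6.60). Among knockout vehicle libraries replicate 1 was highest for LCP1 (5.60 CPM) and replicate 4 for SQSTM1 (214), while replicate 2 was lowest for TK1 (114) and the ERK output list (0.0580, nearest other 0.0886). Under abemaciclib knockout replicate 3 was highest for CCNE1 (6.79 CPM) and CDK2 (36.8), and replicate 4 lowest for SUCLG2 (58.2). Reads were also assigned to ERCC spike-in sequences, which no comparison uses, with 36 to 65 reads in a library over 28 sequences, or 3.06 to 6.28 CPM.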

How the results depend on the processing

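Voom on fractional reads, the restriction to genes of whole reads and the tyrosine list without FAH were chosen only after the data had been seen, and the planned tests of read counts with edgeR and DESeq2 were not run, because 5270 of the 16218 tested genes had whole reads in all libraries. Of 482 alternative values of the counts of genes and lists, FAH and the correlations, 463 stayed within 1.5 times the count, kept the call or lay within 0.05 of the correlation, among them all 304 that left out 1 library. This rule takes each count alone and not the balance of higher and lower genes. After median-of-ratios rescaling the higher share of called genes went from 65.3 to 48.8% for the knockout under vehicle and from 62.2 to 46.9% under abemaciclib. For the drug it went from 38.7 to 50.8% in control and from 28.6 to 52.0% in knockout cells, so this balance depends on the scaling. The 19 values outside the rule follow. Without a filter on low values 494 genes had a positive and 578 a negative interaction, and without the trend in limma 491 a positive one, and the cause was not tested. With abemaciclib in knockout cells 3144 genes were higher and 2905 lower after median-of-ratios rescaling, which raised the median of all genes by 0.0779. They were 3578 and 2715 after quantile normalization, where the cause was not tested. With only the 5270 genes (32.5%) of whole reads in all libraries, fewer genes were tested. Then 1233 were higher and 574 lower in knockout cells under vehicle, 858 and 576 under abemaciclib, 967 and 1451 with the drug in control and 495 and 1307 in knockout cells, and 124 and 269 in the interaction. Of the list calls of these comparisons, in this order, 9 of 22, 13 of 25, 10 of 20, 8 of 17 and 8 of 15 held in this setting and 8, 7, 6, 6 and 4 were lost. The other 5, 5, 4, 3 and 3 were not tested, with fewer than 5 members left. Lists had fewer members here, and whether that or shared reads ended the calls was not tested. With an estimated correlation 9 of 17 list calls held for abemaciclib in knockout cells. The correlation of knockout effects was 0.724 across genes called in either comparison alone, since genes without a call were left out. After quantile normalization CALR was at 0.0228 in knockout cells under vehicle and EPCAM at 0.0262 with abemaciclib in control cells, above 0 and not called, and the cause was not tested. Of 18885 alternative values of named genes 18584 kept their direction and their side of the threshold, 262 lost the call, 37 gained one and these 2 changed direction. Over all settings FAH lay between -1.99 and -1.43 under vehicle and between -2.05 and -1.43 under abemaciclib. Leaving out each library in turn gave 3541 to 4154 higher and 1881 to 2213 lower genes for the knockout under vehicle, and 2569 to 3068 and 1617 to 1836 under abemaciclib. It gave 2892 to 3178 and 4658 to 5190 for the drug in control cells, 1569 to 1867 and 4010 to 4617 in knockout cells, and 627 to 792 and 816 to 1096 for the interaction. The lists called were then 20 to 22, 24 to 25, 19 to 20, 16 to 17 and 15 to 16 in this order of comparisons. The correlation across genes was 0.843 to 0.852 for abemaciclib effects and 0.646 to 0.669 for knockout effects. Replicate numbers did not pair the libraries, since deviations from the group means correlated between -0.0367 and 0.0603 over 24 pairs of the same number, 0 of them over 0.1. Over 72 pairs of different numbers they correlated between -0.0581 and 0.0670. In every other group at once, 0 libraries correlated best with their own number, though some did so in a single group. With a replicate block the higher and lower counts were 4002 and 2121, 3006 and 1828, 3201 and 5029, 1775 and 4437, and 742 and 1003 in the same order, and no list call changed. Depth limits low genes most, since 1 CPM stands for about 10 reads.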

Other observations

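The hypothesis of this part was set down before its test was run; the metallothionein genes, FOS, JUN, JUNB, DUSP4 and the leukocyte markers named here and above were chosen after their values were seen. Of the 4 tested genes of the metallothionein list, which holds small proteins that bind zinc and copper and a zinc transporter, 3 fell and 0 rose with abemaciclib in control cells, and 3 and 0 in knockout cells, with the same counts when adjusted over the list alone. The member not called was SLC30A1 (-0.11 and -0.03), which passed in control cells without control vehicle replicate 3 (-0.17, limma adjusted p = 0.0373). MT2A went from 127 ± 3.54 to 42.6 ± 1.12 CPM in control cells (-1.55, limma adjusted p = 4.2e-26) and from 130 ± 3.43 to 48.7 ± 1.44 CPM in knockout cells (-1.40, limma adjusted p = 6.8e-25). MT1X (-1.01 and -0.55) and MT1F (-1.0 and -0.59) fell in both as well. Of these 4 genes, too few for camera, 4 were higher and 0 lower in knockout cells under the drug (4 and 0 adjusted over the list alone), and 0 and 0 under vehicle. Under the drug MT1F missed the threshold without control abemaciclib replicate 1 (limma adjusted p = 0.0501). Under vehicle MT1X passed as lower after rescaling (-0.19, limma adjusted p = 0.0315) and quantile normalization (0.0385), and SLC30A1 as higher with library weights (0.0495) or without control vehicle replicate 1 or knockout vehicle replicate 3 (0.0453 and 0.0416). The list of ERK pathway output and immediate early genes was not called with abemaciclib in control cells, where 7 of 20 members rose and 6 fell (7 and 6 adjusted over the list alone, median 0.01, camera adjusted p = 0.0831). Of its members FOS, JUN and JUNB, which encode transcription factors induced within minutes of a stimulus, rose there by 0.93, 0.96 and 0.37. JUN rose in knockout cells too (0.40). FOS (0.24, limma adjusted p = 0.0457) and JUNB (0.20, limma adjusted p = 0.0109) passed there, but not in every setting. FOS was at 0.13 without knockout vehicle replicate 4 (limma adjusted p = 0.272). It was lost as well without knockout vehicle replicate 1 (0.0670), knockout abemaciclib replicate 1, 2 or 4 (0.0881, 0.105 and 0.0825) or control abemaciclib replicate 2 (0.0502), with a pseudocount of 0.1 (0.0506), without the filter (0.184) and without the trend in limma (0.0954). JUNB was lost without knockout vehicle replicate 1 (0.15, limma adjusted p = 0.0688), without the filter (0.0848) and without the trend (0.0539). All 3 genes were higher in knockout than in control cells under vehicle (FOS 0.74, JUN 0.49, JUNB 0.54). DUSP4, a phosphatase that acts on ERK, was lower in knockout cells under vehicle (-1.08) and abemaciclib (-1.24), while the same list was not called in either (camera adjusted p = 0.527 and 0.822).

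Apoptosis regulators were not called in any comparison (camera adjusted p between 0.0890 and 0.675). Of 26 members 11 were higher and 1 lower in knockout cells under vehicle, and 4 rose and 6 fell with the drug in control cells, with the same counts when adjusted over the list alone. Heme and iron genes were not called either (camera adjusted p between 0.215 and 0.749), with 4 higher and 1 lower of 21 in knockout cells under vehicle and the same counts when adjusted over the list alone. Among markers of other cell types, 2 of 7 basal genes were higher and 2 lower in knockout cells under vehicle, 2 and 2 of 10 mesenchymal genes, and 0 and 1 of 8 leukocyte genes, with the same counts when adjusted over the list alone. None of the 3 lists was called in any comparison (camera adjusted p from 0.444 to 0.872, 0.152 to 0.885 and 0.0938 to 0.808). Of the 4 tested HEK293-type markers, too few for camera, 2 were higher and 1 lower under vehicle (3 and 1 adjusted over the list alone), the lower one being LIN28A.

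One hypothesis is that the knockout changes of vehicle cells share a part with the abemaciclib changes of control cells. Both comparisons use the control vehicle libraries, which alone give a correlation across genes of 0.50 in 100 simulations without any effect, against 0.501 observed, so the correlation decides nothing here. The covariance was 0.0534, against 0.00492 simulated. With the 4 control vehicle libraries split 2 and 2 between the comparisons, the lowest of the 6 correlations was 0.428 and the highest 0.436, with a mean covariance of 0.0485, and 0.428 to 0.437 without the replication and mitosis lists. Genes are not independent replicates. Of the genes called higher 1896 were shared, against 782 for independent lists of these sizes, and of those called lower 1466, against 659, but shared controls add to both. The split keeps the noise of single control libraries from entering both comparisons. It does not remove a deviation common to all 4 control vehicle libraries, which would move both comparisons the same way. The values go with the hypothesis but cannot tell it from such a deviation. They also do not say which genes carry it or what causes it. Against a large deletion around FAH, the 25 tested genes within 2 Mb of it had a median knockout effect of at least 0.00982 in either treatment. The median knockout effect, averaged over both treatments, of each of 256 windows of 10 Mb with 20 or more tested genes lay within 0.171 of that of all genes. This does not exclude gain or loss of a chromosome region. A change in a part of the cells would move a window by less, and whether they were a clone or a pool is not known. The window furthest off was 160 to 170 Mb of chromosome 3 (-0.171, with 81.8% of 22 genes on that side). The windows on both sides of it were lower too (-0.0871 and -0.0782), as were those from 70 to 100 Mb of chromosome 8 (-0.0985, -0.0685 and -0.0862). Whether these mark a change of copy number was not tested.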
